A study of Homo sapiens with 5 samples.

How the data were processed

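The series holds 5 samples of human osteosarcoma cell lines. SaOS-2, an established osteosarcoma line used as an osteoblast model, was profiled by ATAC-seq in 1 sample, an assay in which a transposase inserts sequencing adapters into accessible DNA. RNA-seq of SaOS-2, U-2 OS, HOS and MG-63, with 1 sample each, is not analysed here. A second list of open regions came from DNase-seq of primary human osteoblasts, in which the nuclease DNase I cuts accessible DNA. Per the labels' series design, the authors re-called these regions from public data of 2 libraries. It belongs to none of the 5 samples.

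The ATAC-seq library was made with a smaller transposition volume, a higher transposase concentration and 12 cycles of PCR, and was sequenced in paired reads of 125 bp, per the labels' protocols. The submitters' processing notes list Trimmomatic and BWA 0.7.15 without saying for which assay, and list GRCh37, hg19 and hg38 as genome builds. The names of both region lists give hg19 and a false discovery rate (FDR) of 0.01, and the contig names in the SaOS-2 list are those of hg19. The region caller's version and any filter on duplicates, mitochondrial reads or transposase offset are not given in the sources used here. Nor do these sources say whether the DNase-seq libraries were pooled before calling or merged afterwards. These steps could change the number and width of the regions, and they may differ between the lists, whose names differ in the caller's output version.

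The deposited SaOS-2 list gives a start, an end, a score and the −log10 FDR of each region. The deposited score was within 1 of 10 times the −log10 FDR in every row, so only the −log10 FDR was used. The deposited −log10 FDR values ran from 2.00 to a cap of 100. The deposited osteoblast list gives chromosome, start and end alone. Neither list gives read counts, so the sequencing depth behind a region is unknown. A region missing from a list was not called at this threshold, which does not show that the DNA was closed.

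Regions on chromosomes 1 to 22 and X were used. Starts were read as counted from 0, and positions are printed counted from 1. An overlap was at least 1 shared base. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Because neighbouring regions are not independent, the 2 main shares were also given a 95% range over 1000 bootstrap draws of 5 Mb blocks. Chance overlap was taken from 100 random placements, in which all regions of the other list were moved by 1 random offset per chromosome and wrapped at the chromosome's last region (circular shifts). In a second set of 100 placements the other list was moved as a whole by 2 to 20 kb (local shifts), which keeps the regional density. The block of widths set apart below lies between the largest rise and the largest later fall in the number of osteoblast regions from 1 width to the next, with the most common width left out, and was chosen after seeing the data. Chromosome shares, 100 kb windows, region widths, distance from the chromosome ends (the first coordinate and the last region of a chromosome) and the number of osteoblast regions within 50 kb were then compared. Intervals of a ratio of chromosome shares used the normal approximation of the log ratio and cover counting error only. There was 1 list per assay, so no test across samples was possible, no p-value is given, and cell source, assay and caller settings differ together.

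Gene, promoter, gene-list and motif comparisons had been planned for the case that an annotation and sequence of hg19 could be used. None was used here, and coordinates were not converted between builds, so regions are named by position. The rule for named items, fixed before the data were examined together with the main comparisons and most of their alternatives, was the 3 chromosomes with the highest and the 3 with the lowest ratio of region shares, and per list the 5 windows of 100 kb with the most covered bases and no region of the other list. These alternatives were other overlap rules, stricter or equally long lists, regions set to 150 bp, placement with bedtools shuffle, covered bases in place of region numbers, and unshared regions alone.

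The overlap code was tested on simulated lists of 73301 and 170338 regions before use. With 30% of regions planted on the other list, 32.7% overlapped where 32.6% were expected. Independent lists gave a fold of 1.02 over circular shifts and 1.02 over local shifts. The simulated regions were placed at random without clusters or gaps. This tested the counting, not how well the shifts give chance overlap for clustered lists. All 4 overlap rules returned the same regions as bedtools 2.31.1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.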

Results

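Open chromatin was compared between SaOS-2 osteosarcoma cells (ATAC-seq, 1 sample) and primary human osteoblasts (DNase-seq, 1 list over 2 libraries), in a series on the genetics of osteoporosis that used both as maps of regulatory DNA in bone-forming cells. The SaOS-2 list held 73301 regions on chromosomes 1 to 22 and X, which covered 26.2 Mb. The osteoblast list held 170338 regions covering 57.6 Mb, 2.32 times as many regions and 2.20 times the length. Median widths were close, at 270 bp in SaOS-2 (quartiles 159 and 485) and 289 bp in osteoblasts (quartiles 245 and 349). The median −log10 FDR of the SaOS-2 regions was 5.29, with quartiles of 3.23 and 10.8. Neither list had replicates, and the read depth behind them is unknown.

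The first comparison asked how much of the open chromatin of the cell line was also called in primary osteoblasts. Of the 73301 SaOS-2 regions, 32670 overlapped an osteoblast region, a share of 44.6% (95% interval 44.2 to 44.9, and 43.1 to 46.1 over 5 Mb blocks). The other 40631 SaOS-2 regions met no osteoblast region. In the other direction, 32236 of the 170338 osteoblast regions met a SaOS-2 region, a share of 18.9% (18.7 to 19.1, and 18.1 to 19.8 over blocks). The lists had 10.1 Mb in common, 13.7% of the bases in either. The shares depended on the overlap rule and on which regions were kept. When 50% of both regions had to overlap they were 21.8% and 9.39%. With the top 50000 regions of each list they were 30.9% and 30.3%. The osteoblast list gives no score, which leaves width as the only measure to rank its regions by. Wide osteoblast regions were shared more often (below), so the rise from 18.9% to 30.3% does not reflect list length alone.

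The overlap was far above chance placement in both directions. When the osteoblast regions were shifted along each chromosome, 3.85% ± 0.13 (SD, n = 100 shifts) of the SaOS-2 regions met one, so that the observed share was 11.6 times the shifted one. When they were moved by 2 to 20 kb, which kept the regional density, 6.42% ± 0.35 (SD, n = 100 shifts) met one, a fold of 6.95. Each of these local shifts used the same offset on all chromosomes. Their SD is therefore a spread over the distances moved and is unlike that of the circular shifts. None of the 100 shifts of either kind reached the observed share. For osteoblast regions the corresponding folds were 11.5 and 6.95. The fold over local shifts depended on the density of osteoblast regions. With up to 5 of them within 50 kb it was 20.1 for SaOS-2 and 21.2 for osteoblast regions. With more than 50 it was 2.20 and 1.94. Chance for SaOS-2 regions was 40.3% there, which by itself keeps their fold low. For osteoblast regions chance was 3.87%, and the share itself fell from 27.3% to 7.50%. The fold of SaOS-2 regions over circular shifts was 24.8 when 50% of both regions had to overlap, 19.9 with 50% of the counted region, 19.1 with the midpoint inside, 18.5 with regions of 150 bp and 17.9 with the top 50000 of each list.

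SaOS-2 regions with stronger calls were shared more often. In the lowest decile by −log10 FDR, 33.1% (32.0 to 34.2) of 7331 regions overlapped an osteoblast region. The share rose in each following decile and reached 65.4% (64.3 to 66.5) of 7330 regions in the highest, where the −log10 FDR was 21.45 or more. Stronger regions were also wider, with a median of 79 bp in the lowest decile and 819.5 bp in the highest, and a wider region meets others more often by chance. Measured against local shifts, the fold was 6.95 in the lowest decile, 6.57 in the sixth and 7.53 in the highest. Shared SaOS-2 regions had a median width of 352 bp and a median −log10 FDR of 6.82, against 221 bp and 4.51 for those not shared.

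**Figure D1:**
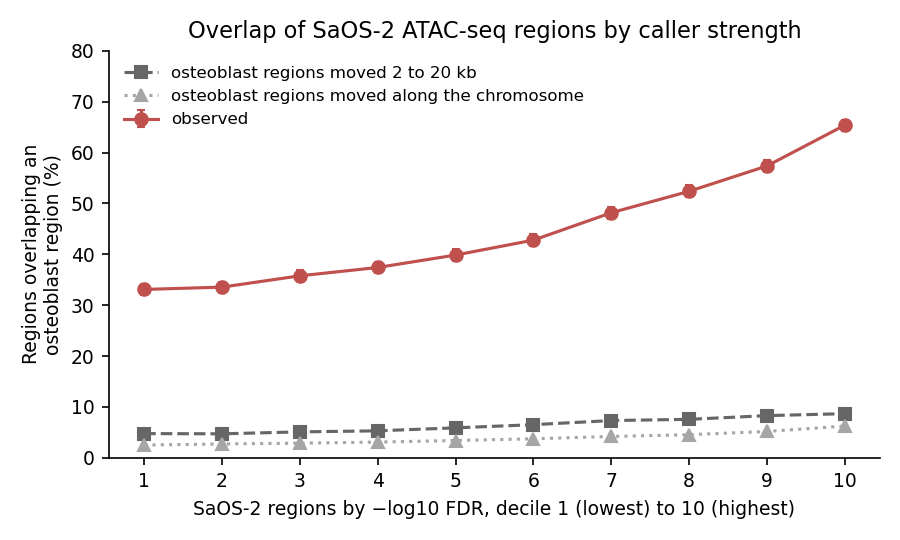
Share of SaOS-2 ATAC-seq regions (y axis, percent) that overlap an osteoblast DNase-seq region, by decile of the −log10 FDR (x axis), with exact 95% intervals, and the mean share over 100 local and 100 circular shifts. The observed share goes from 33.1% in the lowest decile to 65.4% in the highest, and the local shifts from 4.76% to 8.68%.

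At the top of the SaOS-2 list, 118 regions stood at the cap of 100, and 82 of them overlapped an osteoblast region (69.5%, 60.3 to 77.6). Of the 36 capped regions without an osteoblast partner, 12 lay on chromosome 1. The widest SaOS-2 regions were at hg19 chromosome 12, 133790955 to 133800024 (9070 bp), and chromosome 13, 51168257 to 51176710 (8454 bp). The chromosome 12 region overlapped an osteoblast region and the chromosome 13 region did not, while the SaOS-2 region directly before the latter, at 51163226 to 51168254 (5029 bp), did.

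Osteoblast regions were shared with SaOS-2 in a way that depended on their width. Of the 3303 osteoblast regions over 1000 bp, 64.6% (63.0 to 66.3) met a SaOS-2 region, and of the 15738 regions of 501 to 1000 bp, 46.5% did (45.8 to 47.3). The 97367 regions of 227 to 326 bp, 57.2% of the list, were shared in 10.5% of cases (10.3 to 10.7). Narrower regions were shared more often than these, with 34.0% of 1409 regions of 202 to 226 bp and 27.0% of 11033 regions of 50 to 200 bp. The 12058 regions of exactly 201 bp were shared in 7.75% (7.28 to 8.25). Wider regions also meet others more often by chance, and against local shifts the order differed. The fold was 18.5 at 202 to 226 bp, 18.2 at 50 to 200 bp, 11.5 at 501 to 1000 bp, 10.6 over 1000 bp, 8.76 at 327 to 500 bp, 4.29 at 227 to 326 bp and 3.19 at 201 bp. With chance at 6.10% over 1000 bp, the fold there could not reach 18.2 even if every region were shared. In the SaOS-2 list the share that met an osteoblast region was 33.3% at 50 to 200 bp and 80.6% (79.0 to 82.1) over 1000 bp, while the fold over local shifts was 7.11 and 7.00. Without the osteoblast regions of 227 to 326 bp, the shared part was 32.3% of the SaOS-2 list and 30.1% of the osteoblast list.

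**Figure D2:**
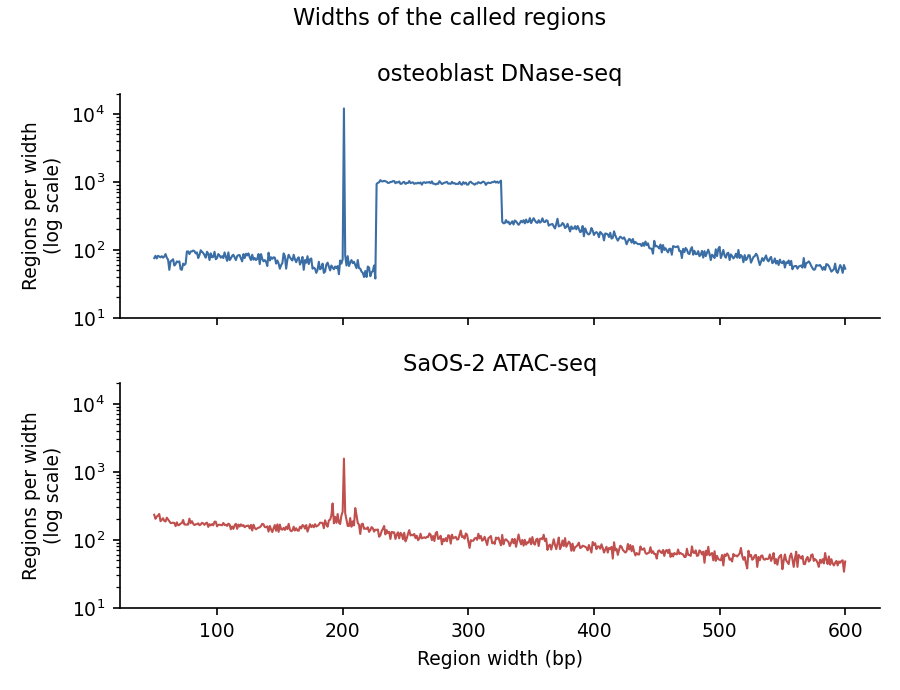
Number of regions (y axis, log scale) at each width from 50 to 600 bp (x axis) in the osteoblast list (top) and the SaOS-2 list (bottom). Osteoblast regions number 905 to 1064 at each width from 227 to 326 bp, against 38 at 226 bp and 260 at 327 bp, and both lists have a spike at 201 bp.

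The next comparison was where along the chromosomes each cell source had open regions. Osteoblast regions were concentrated towards chromosome ends, and SaOS-2 regions were spread more evenly. The outer 5 Mb at each chromosome end, 7.58% of the chromosome span, held 21.5% (21.3 to 21.7) of the osteoblast regions and 8.43% (8.23 to 8.63) of the SaOS-2 regions, a ratio of 2.56. The osteoblast list had 224 regions per Mb at 1 to 2 Mb from an end and 39.0 per Mb at 40 to 80 Mb, while SaOS-2 had 30.4 and 22.3 per Mb. Of the osteoblast regions in the outer 5 Mb, 10.4% (10.1 to 10.8) met a SaOS-2 region, against 21.3% (21.04 to 21.5) of the inner ones. Of the SaOS-2 regions in the outer 5 Mb, 64.9% (63.7 to 66.1) met an osteoblast region, against 42.7% (42.3 to 43.1) of the inner ones. Chance overlap was also higher near the ends, at 16.9% of outer and 5.45% of inner SaOS-2 regions after local shifts. The folds were 3.85 for outer and 7.83 for inner regions. With chance at 16.9%, the outer fold could not reach 7.83 even if every region were shared, so the order of these folds decides nothing. For osteoblast regions the folds were 3.62 and 7.93. Their chance overlap was 2.88% in outer and 2.68% in inner regions, so no such limit applies, and outer osteoblast regions were shared less relative to chance. Distances were taken from the first coordinate of each chromosome and from its last region. The span and the densities per Mb therefore count stretches without a region in either list, such as the first 5 Mb of chromosome 14. The 7.58% is thus only a rough yardstick.

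**Figure D3:**
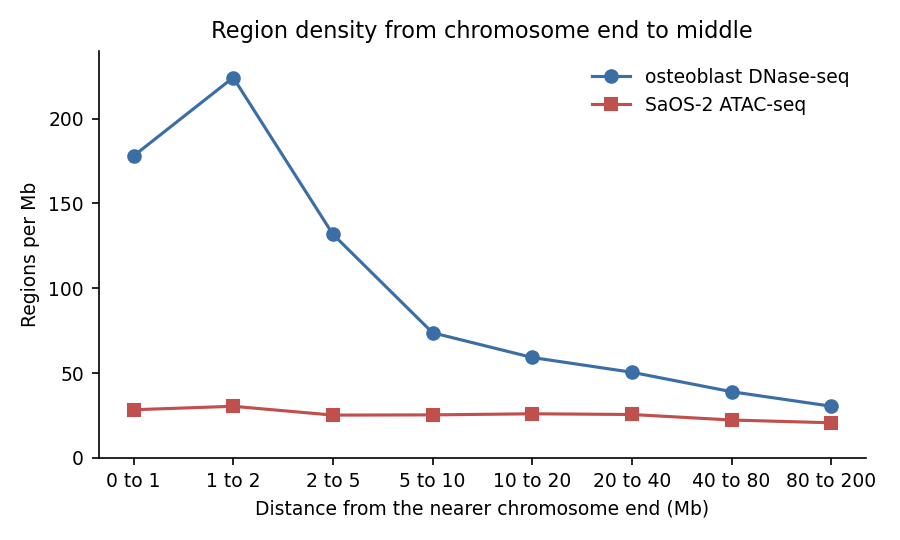
Regions per Mb (y axis) by distance from the nearer chromosome end (x axis, bins in Mb of unequal width) for both lists, over chromosomes 1 to 22 and X. The osteoblast density goes from 224 per Mb at 1 to 2 Mb to 30.4 per Mb beyond 80 Mb, and the SaOS-2 density from 30.4 to 20.7 per Mb.

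Chromosomes 6, 4 and 13 held a larger part of the SaOS-2 list than of the osteoblast list. Chromosome 6 had 6.99% (6.81 to 7.18) of the SaOS-2 regions and 4.49% (4.39 to 4.59) of the osteoblast regions, the highest ratio of shares at 1.56 (1.504 to 1.61). The ratio was 1.53 (1.47 to 1.59) for chromosome 4 and 1.47 (1.39 to 1.56) for chromosome 13. Chromosomes 22, 19 and 16 had the lowest ratios, at 0.509 (0.479 to 0.541), 0.533 (0.509 to 0.557) and 0.629 (0.6003 to 0.659). SaOS-2 had 29.99 regions per Mb on chromosome 6, 20.3 on 4, 17.6 on 13, 23.8 on 22, 37.4 on 19 and 23.98 on 16. Osteoblast densities, in the same order, were 44.8, 30.9, 27.7, 109, 163 and 88.6 per Mb. Chromosome 19 had the highest SaOS-2 density of all 23 chromosomes. SaOS-2 density was lower on 4 and 13 than on 22 and 16, so the ratios do not rank SaOS-2 density. Over all 23 chromosomes, 12 ratios had an interval above 1 and 9 an interval below 1, with counting error alone in the interval. SaOS-2 regions were shared most on chromosomes 19 and 22, at 71.8% (69.9 to 73.7) and 64.3% (61.5 to 67.0). Osteoblast regions were dense on both, and chance overlap rises with that density. After local shifts it was 1.22% of SaOS-2 regions with up to 5 osteoblast regions within 50 kb and 40.3% with more than 50. No chance value was taken per chromosome, so these shares do not show that the lists are more alike there. On chromosome 6, 39.0% (37.6 to 40.3) of SaOS-2 regions were shared, and osteoblast regions were shared there more than on any other of the 23 chromosomes, at 25.8% (24.8 to 26.8).

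The ratios were also taken at places where osteoblast regions were sparse. This limit is set on the list that forms the denominator, which by itself draws the ratios together. With at most 5 osteoblast regions within 50 kb, a limit chosen after seeing the data, the ratio was 1.23 (1.16 to 1.30) for chromosome 6, 1.13 (1.07 to 1.19) for chromosome 4, 1.09 (1.01 to 1.18) for chromosome 13, 0.748 (0.672 to 0.833) for chromosome 16, 0.828 (0.724 to 0.947) for chromosome 19 and 0.720 (0.584 to 0.887) for chromosome 22. Of the 23 chromosomes, 16 stayed on the same side of 1.

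**Figure D4:**
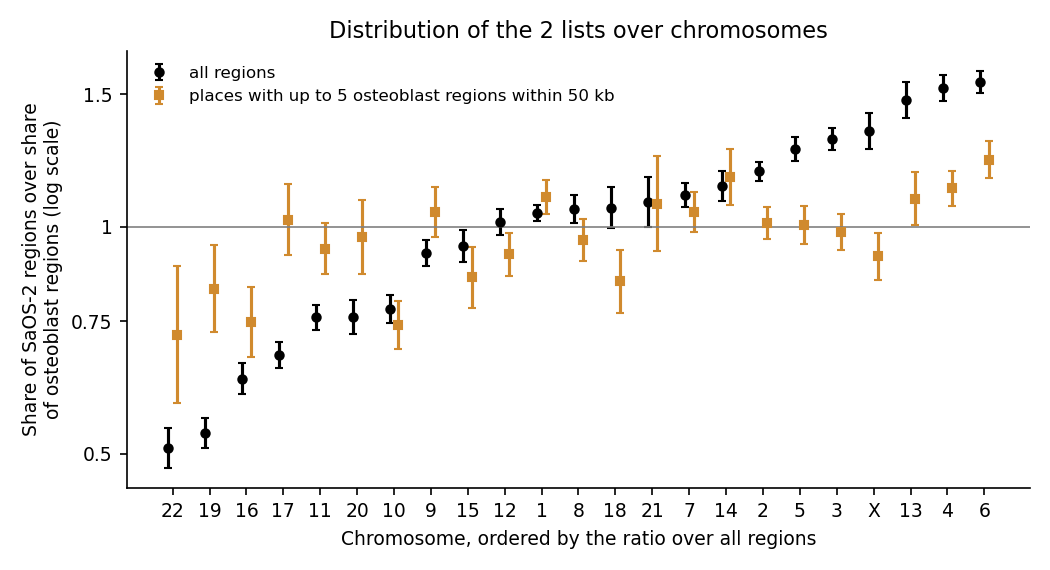
Share of SaOS-2 regions on each chromosome divided by the share of osteoblast regions (y axis, log scale), with 95% intervals for counting error, for all regions and for places with at most 5 osteoblast regions within 50 kb. Over all regions the ratio goes from 0.509 on chromosome 22 to 1.56 on chromosome 6, and at sparse places from 0.720 to 1.23 on the same chromosomes.

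In windows of 100 kb, most of the genome with any open region had regions of both lists. Of 24321 such windows, 17511 (72.0%) held both, 3993 (16.4%) held osteoblast regions alone and 2817 (11.6%) held SaOS-2 regions alone. No chance value is given for windows, and the share with both depends on how many windows each list fills. The 5 windows with the most osteoblast bases and no SaOS-2 region all lay near the start of chromosome 5 or 7. On chromosome 7, 53 osteoblast regions covered 22554 bp between 500001 and 600000, 56 regions covered 20460 bp between 400001 and 500000, and 44 regions covered 17474 bp between 100001 and 200000. On chromosome 5, 62 regions covered 20441 bp between 1000001 and 1100000, and 53 regions covered 18383 bp between 1100001 and 1200000. In the first chromosome 7 window, 28 of the 53 regions were 227 to 326 bp wide.

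The SaOS-2 windows without an osteoblast region were sparser. The first, at chromosome 19, 28100001 to 28200000, held 16 regions over 8578 bp, with a median −log10 FDR of 6.76. The next 100 kb held 23 SaOS-2 regions over 20496 bp, 2 of them at the cap, beside 2 osteoblast regions. Both windows lay shortly after the longest region-free stretch of chromosome 19, which ended at 27998441, and mapping artefacts there were not checked. At chromosome 1, 500001 to 600000, 4 SaOS-2 regions covered 6035 bp with a median −log10 FDR of 100. This stretch of hg19 is known to include a nuclear copy of mitochondrial DNA, which was not checked here. Chromosome 12, 5300001 to 5400000, had 9 regions over 3861 bp. Chromosome 18, 42700001 to 42800000, had 8 regions over 3785 bp. Chromosome 1, 77800001 to 77900000, had 9 regions over 3625 bp, with a highest −log10 FDR of 62.6. Numbers of windows open in 1 list alone depend on the length of the lists, and 1748 osteoblast windows and 6566 SaOS-2 windows were open alone once the osteoblast regions of 227 to 326 bp were left out, which turned the order of the lists.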

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

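The SaOS-2 list held 20 regions on 9 unplaced or unlocalised contigs, which no comparison uses. They were picked out because they are a signal outside the chromosomes compared, above the 3 that a count of 0 allows, and no control list exists for them. Their median −log10 FDR was 6.97, and 9 of them lay on 1 contig that the hg19 assembly assigns to chromosome 1. No biological explanation was tested. With 1 list per assay, samples could not be compared for outlying values or for differing effects.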

How the results depend on the processing

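Alternatives that leave out the regions of 227 to 326 bp, leave out chromosome ends, merge regions, shift locally or change the windows, the limit to sparse places and the ratio of window numbers were chosen after seeing the data. Of 83 alternative values, 1 reversed its direction, 18 stayed within the counting error or 1.5 times the count, and 64 moved. The share of SaOS-2 regions that overlapped (44.6%), the share of osteoblast regions that overlapped (18.9%) and the fold over shifts (11.6) were, in this order, 21.8%, 9.39% and 24.8 when 50% of both regions had to overlap, 34.9%, 14.1% and 19.9 with 50% of the counted region, 38.9%, 16.1% and 19.1 with the midpoint inside, and 32.9%, 13.9% and 18.5 with 150 bp regions. The stronger 50% of the SaOS-2 list against the wider 50% of the osteoblast list gave 40.1%, 18.1% and 14.2. The top 50000 of each, for which the osteoblast list can be ranked by width alone, gave 30.9%, 30.3% and 17.9. Leaving out the regions of 227 to 326 bp gave 32.3%, 30.1% and 16.9, and leaving out the outer 5 Mb gave 42.7%, 21.3% and 14.3. Local shifts gave a fold of 6.95 and bedtools shuffle 10.9. Lower shares follow from a stricter rule or a shorter list by construction. The lists limited to 50% held 36650 SaOS-2 and 85169 osteoblast regions, the latter over 37.9 Mb. The difference in median width between shared and unshared regions, 131 bp in SaOS-2 and 69 bp in osteoblasts, was 188.5 and 102 bp when 50% of both regions had to overlap. The ratio for chromosome 6 was 1.87 in unshared regions, 1.67 without the regions of 227 to 326 bp, 1.47 without the outer 5 Mb and 1.23 at sparse places. For chromosome 22 it was 0.308 in unshared regions and 0.720 at sparse places. Chromosome 6 did not have the highest ratio in every setting: it was chromosome 4 in unshared regions, 13 in the lists limited to 50% and 21 without the outer 5 Mb, and chromosome 19 was lowest in unshared regions and without the regions of 227 to 326 bp. Where the setting's construction does not account for a shift, the cause was not tested. Windows open in SaOS-2 alone numbered 6517 at 50 kb, 29 at 1000 kb and 6566 without the regions of 227 to 326 bp, and windows open in osteoblasts alone 10663, 65 and 1748. The ratio of these numbers, 0.705 for windows of 100 kb, was 0.446 at 1000 kb and reversed to 3.76 without the regions of 227 to 326 bp, which shortens the osteoblast list by construction. The alternatives fixed beforehand for promoters, gene loci and motifs were not run, since no hg19 annotation or sequence was used here. No paired analysis was possible because there is 1 list per assay. The unknown read depth limits every count: a deeper library calls more regions.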

Other observations

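The tests below on background calls in the regions of 227 to 326 bp, on their densest neighbourhoods and on the density of osteoblast regions as the cause of the chromosome ratios, and the contrasts between sides of a chromosome, were chosen after the result was seen. The others were written down before their result was seen, although the patterns they address had been seen.

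On the short arm of chromosome 8, osteoblast regions met SaOS-2 regions less often than their width and neighbourhood predicted. Of 2396 osteoblast regions before the longest region-free stretch of this chromosome (hg19 43751653 to 46941177 between region midpoints), 278 met a SaOS-2 region, 0.572 times the number expected from their width and neighbour class (95% range over 5 Mb blocks 0.455 to 0.728). This was the lowest of 43 such chromosome sides with at least 200 osteoblast regions, of which 11 had a range below 1, among them both sides of chromosomes 10 (0.821 and 0.809) and 18 (0.759 and 0.743), and 7 a range above 1. The 11 include the earlier sides of 18, with 3 blocks, and of 22, with 2. Draws from so few blocks only return the block values, so those 2 ranges decide nothing. After the stretch the chromosome 8 ratio was 1.05 (0.906 to 1.23) over 4445 regions, and over the whole chromosome it was 0.883 (0.741 to 1.04). The arms overlapped in their 5 Mb blocks, which ran from 0.286 to 0.991 on the short arm and from 0.516 to 1.78 on the long arm. The long-arm blocks between 50000001 and 70000000 lay between 0.516 and 0.646, and those between 105000001 and 135000000 between 1.32 and 1.78. By whole chromosome, 5 (1, 3, 6, 14 and 21) had a range above 1 and 5 (10, 11, 16, 18 and X) a range below 1. These ranges treat 5 Mb blocks as independent, but neighbouring blocks had a lag-1 correlation of 0.349, so the ranges may be too narrow. Bounds next to 1, such as 0.9998 for 16 and 1.004 for 21, therefore decide little. The SaOS-2 windows with the most regions held 28 (chromosome 2, 102400001 to 102500000, beside 4 osteoblast regions) and 25, against 116 in the fullest osteoblast window (chromosome 10, 135000001 to 135100000, beside 3 SaOS-2 regions).

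The widths of the osteoblast list have a sharp-edged block. Each of the 100 widths from 227 to 326 bp has 905 to 1064 regions, a variance of 1.197 times the mean, while 226 bp has 38 and 327 bp has 260; SaOS-2 has no such block. The regions of these widths cannot all be chance positives, since they met SaOS-2 regions 4.29 times as often as after local shifts. Regions like those of neighbouring widths, shared at 34.0% (202 to 226 bp) and 27.7% (327 to 500 bp), may lie among them, however. The fold therefore cannot tell whether the excess that forms the block is chance positives. Among the 6843 regions of the block that have more than 50 osteoblast regions within 50 kb, 3.27% (2.86 to 3.72) met a SaOS-2 region against 3.41% after shifts, a fold of 0.961. For these, background calls or sites closed in SaOS-2 may account for the lack of sharing. Whether the block holds weak sites stays open: SaOS-2 regions that met it had a median −log10 FDR 0.992 times that of regions that met wider ones alone, between the bounds set for either answer, and a fixed step of the region caller was not tested.

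Osteoblast regions crowd near chromosome ends far more than SaOS-2 regions, of which 8.43% (8.23 to 8.63) lay in the outer 5 Mb, slightly above its 7.58% of the span. That span counts stretches without any region, so the small difference for SaOS-2 decides little. The 73301 widest osteoblast regions still had 22.3% in the outer 5 Mb, 2.64 times the SaOS-2 share. This cut cannot rule out the longer list as the reason, because it was made by width. From 227 bp upwards, wider osteoblast regions lay near the ends more often, from 19.6% at 227 to 326 bp to 28.5% over 1000 bp. The outer regions were not all background calls, as they met SaOS-2 regions 3.62 times as often as after local shifts, against 7.93 for inner regions. That fold cannot tell whether background calls make up the crowding itself. Regions of 227 to 326 bp with more than 50 osteoblast regions within 50 kb, 70.6% of them in the outer 5 Mb, had a fold of 0.961. A difference between DNase I and transposase libraries in base composition, a difference in caller settings and a difference between osteoblasts and the tumour line all stay open, untested, since sequence was not used and these differ together.

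Whether the chromosome ratios follow the density of osteoblast regions stays open: at sparse places the SD of the log2 ratio was 0.453 times that over all regions, but those places were chosen by the count in the denominator, so this value decides nothing. On chromosome 6, SaOS-2 met 1.15 times (1.06 to 1.24) the osteoblast regions expected from width and density. By arm this was 1.22 (1.09 to 1.37) on the short and 1.08 (0.959 to 1.19) on the long arm, whose range includes 1. The range of the whole chromosome lies above 1, the outcome set beforehand for width and density not being enough. It may be too narrow, however, and chromosome 6 was picked for its high ratio in the same lists. Width and density are therefore not ruled out as an account of the sharing there. Of the other chromosomes with the highest or lowest ratios, the range included 1 for 4 (0.988, 0.897 to 1.10), 13 (0.979, 0.840 to 1.13), 19 (1.00, 0.892 to 1.11) and 22 (0.920, 0.802 to 1.003), and was just below 1 for 16 (0.927, 0.863 to 0.9998). The later sides of 4 (1.08, 1.03 to 1.14) and 19 (1.12, 1.01 to 1.199) lay above 1 and the earlier side of 16 (0.862, 0.785 to 0.981) below it. The earlier side of 22 gave 0.927 (0.676 to 0.989), but that range rests on 2 blocks and decides nothing. Neighbouring 5 Mb blocks were alike in this ratio, with a lag-1 correlation of 0.349 across 574 blocks (which are not independent samples) against at most 0.0678 in 100 random orders. That would be consistent with a broad regional property of SaOS-2, for which its abnormal copy number is a candidate explanation, but regional chromatin activity or base composition predicts the same and was not separated.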
